A study of Mus musculus with 4 samples.

How the data were processed

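Single-cell RNA sequencing was done on liver tumours of male C57BL/6 mice, taken 10 weeks after hydrodynamic tail vein injection at an age of 18 weeks. The injected plasmids carried c-MYC and AKT with an empty vector or KLF2, and SB100X, a transposase that inserts them into the genome of the liver cells that take them up. The series has 4 libraries, each from a mouse of its own: vector replicates 1 and 2, and KLF2 replicates 1 and 2. Per the labels the tumours were minced, digested with enzymes for 30 min and filtered, and the libraries were made with a DNBelab C Series droplet kit, which tags each molecule with a unique molecular identifier (UMI).

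The deposited values are UMI counts per gene and cell barcode, whole numbers that were not normalised. Per the file headers the matrices of counts were written by PISA v1.0, and the genome build was GRCm38 according to the submitters. The aligner, the gene annotation and the rule by which the authors called cells are not given in the sources used here. For vector replicate 1 only its barcodes and gene list were used, and no matrix of that library was analysed here. The comparisons therefore set 1 vector library against 2 KLF2 libraries. Each library listed its own set of genes, and a gene missing from a list was taken as 0 in that library. The lowest total per barcode was 522 UMIs in vector replicate 2 and 1000 in each KLF2 library, so the barcodes had been selected at different depths.

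Cells with at least 300 genes and at most 25% mitochondrial UMIs were kept. Doublet calling with Scrublet in scanpy 1.11.5 called 2 of 8403 vector cells (0.024%) and none of the KLF2 cells, too few for the method to have worked on these libraries. An added alternative removed the 5% of cells with the highest doublet scores. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were used, and a graph of 15 neighbours was clustered by Leiden (leidenalg 0.10.2) at resolution 1.0. Clusters were named from marker lists. The mean log2 change of a type's markers against all other cells, with a prior of 20 CPM (UMI counts scaled to the total of the library), had to reach 1.0 and lead the next type by 0.5. At least 3 markers had to be raised and found in at least 25% of the cells. T and NK cells, the macrophages, monocytes and dendritic cells, and B and plasma cells were joined into families after seeing the data, since their separate names changed between resolutions. The tumour/parenchymal compartment, called the compartment, was also defined after seeing the data. It holds the hepatocyte-lineage-like and cholangiocyte-like clusters and the unnamed clusters with less than 100 CPM of Ptprc, the pan-leukocyte gene.

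UMIs were summed per library and class, and classes with at least 50 cells in each of the 3 libraries were tested with the edgeR 4.0.16 quasi-likelihood test (TMM scaling, filterByExpr, Benjamini-Hochberg adjusted p at 0.05). The spread came from the KLF2 libraries alone, with 1 residual degree of freedom moderated across genes, and the vector library was assumed to vary like them. A total of 43 gene lists were tested with limma 3.58.1 camera at a preset correlation of 0.01, where at least 5 members were tested. They were tested again with an estimated correlation, which in the fits within a class rested on 1 residual degree of freedom. Hardly any list could pass on 1 degree of freedom. Not passing there therefore does not decide whether correlation between genes accounts for a change. The gene and marker lists, the tests, the filters and the rule for named genes were chosen before the data were examined. By that rule, genes past 0.05 with a mean of at least 30 CPM and at least 2-fold apart from vector in each KLF2 library were ranked by log2 fold change. The 12 highest rises and 12 deepest falls were taken in the compartment and in hepatocyte-lineage-like cells and 5 each in the other classes, with up to 4 members of each list (2 where none passed). Predicted genes, Rik symbols, mitochondrial and ribosomal protein genes were left out. Hepatocyte-lineage-like cells numbered 20 in KLF2 replicate 1, under the minimum of 50, so for them the rule was used without a test, and a fit of all 3 libraries whatever their cells was added after seeing the data. Their lists were set beside random lists matched on expression, after seeing the data, with vector replicate 2 against KLF2 replicate 2 and 10 CPM added to each value. Shares of cells have Wilson 95% intervals. For a library without cells of a class, the upper limit given is instead 3 cells over all cells of that library. Folds against a group without UMIs are lower bounds from a floor of 3 counts over that group. For the untested 2-fold counts in hepatocyte-lineage-like cells the floor of 3 counts was set in each library. Intervals and floors cover counting error only. CPM in the text were computed over the UMIs of the class in that library. Gene positions come from the GENCODE annotation of GRCm38.

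Recovery was tested on simulated data at the depth and spread of each class. Of genes changed 2-fold, the test recovered 0% in the compartment, 16% in T/NK, 14.6% in endothelial, 6.38% in myeloid, 3.3% in B/plasma, 2.11% in mesenchymal and 0% in neutrophil classes. At 4-fold these shares were 31.2%, 63%, 74%, 67%, 51.1%, 33.7% and 2.74%. At most 5 unchanged genes were called in any class. The simulated vector library varied like the KLF2 libraries and had no shift of its own. The simulation therefore does not cover false calls from differences in preparation or processing of vector replicate 2.

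The alternatives fixed in advance were RLE size factors, DESeq2 1.42.0, limma-voom for gene lists, no low-count filter, cells thinned to 1000 UMIs before summing, equal cells per library, no doublet removal, 500 genes, 10% mitochondrial UMIs, Leiden resolutions of 0.5 and 2.0, other thinning depths and leaving out each KLF2 library. Alternatives chosen after seeing the data were no mitochondrial limit, removal of the top 5% of doublet scores, mitochondrial and rRNA-overlapping genes left out, limma-voom for counts of genes, only those clusters with at least 50 cells in each library, and all 3 libraries whatever their cells for hepatocyte-lineage-like cells. Python 3.11.15 and R 4.3.3 were used.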

Results

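Liver tumours driven by c-MYC and AKT, with or without overexpression of KLF2, a flow-responsive transcription factor best known from endothelium and quiescent lymphocytes, were profiled cell by cell to ask how KLF2 changes cell composition, plasticity-related tumour states and gene programmes. Vector replicate 2 held 45594544 UMIs in 12852 barcodes, KLF2 replicate 1 held 95374838 UMIs in 6282 and KLF2 replicate 2 held 125458473 UMIs in 11240. The median barcode had 2373 UMIs and 631 genes in the vector library, 8784 UMIs and 2378 genes in KLF2 replicate 1, and 5724.5 UMIs and 1731 genes in KLF2 replicate 2. Mitochondrial transcripts made up a median of 16.3% of a barcode's UMIs in the vector library against 0.227% and 0.35% in the KLF2 libraries. Filtering removed 34.6% of the vector barcodes and 1.16% and 1.22% of the KLF2 barcodes, leaving 8401, 6209 and 11103 cells. Gm42418, a gene that overlaps rRNA, took 25.6%, 12.1% and 15.8% of the UMIs.

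The first comparison asked which cell types made up the tumours. T/NK-like and endothelial-like cells dominated the vector library. The KLF2 libraries consisted mostly of compartment cells, which are hepatocyte-lineage-like, cholangiocyte-like or unnamed with little Ptprc. The unnamed part includes a cluster led by the blood gene Hbb-bs, with 4.93% and 12.7% of the cells of KLF2 replicates 1 and 2. It also includes a cluster led by the nuclear RNA Malat1, with 7.49% and 10.1%. T/NK-like cells were 41.2% (40.2 to 42.3) of the vector cells, against 1.51% (1.24 to 1.85) and 3.59% (3.26 to 3.95) in KLF2 replicates 1 and 2. Endothelial-like cells were 20.5% (19.6 to 21.3), 1.58% (1.30 to 1.92) and 2.30% (2.03 to 2.59), and compartment cells were 7.64% (7.09 to 8.23), 83.9% (83.0 to 84.8) and 75.03% (74.2 to 75.8). Within the compartment, hepatocyte-lineage-like cells were 7.61% (7.06 to 8.19) of the vector cells and 0.322% (0.209 to 0.497) and 0.477% (0.365 to 0.624) of the KLF2 cells. Cholangiocyte-like cells, with the biliary keratins Krt19 and Krt7, were 5.69% (5.14 to 6.29) and 11.5% (10.9 to 12.1) of the KLF2 cells and 0 of 8401 in vector, which allows a share of up to 0.0357%.

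Among the other types, B/plasma-like cells were 3.51% (3.14 to 3.93) in vector and 1.59% and 1.32% in the KLF2 libraries, and mesenchymal-like cells were 4.26% (3.85 to 4.72), 1.32% and 1.53%. Neutrophil-like cells were 0.833% (0.66 to 1.05), 0.934% and 1.29%. Myeloid-like cells were 8.13% (7.57 to 8.73), 9.08% (8.39 to 9.82) and 14.7% (14.1 to 15.4), but the order turned with a minimum of 500 genes (15.2%, 8.40% and 13.1%). With at most 10% mitochondrial UMIs the vector share (12.1%) lay between those of the KLF2 libraries (5.43% and 12.8%). Unnamed cells outside the compartment were 13.9% of the vector cells and 0.032% and 0.207% of the KLF2 cells, and with 500 genes they were 0 of 6774 (up to 0.0443%), 0.745% and 2.01%. Shares were not tested between the groups, and the intervals cover counting error and not differences between mice.

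**Figure D1:**
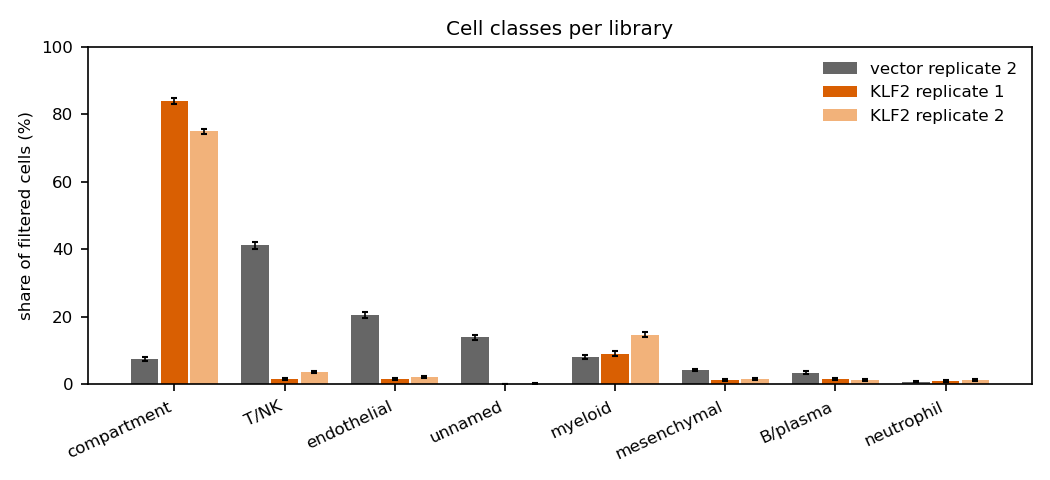
Share of filtered cells (%) in each cell class for vector replicate 2 and KLF2 replicates 1 and 2, with Wilson 95% intervals as error bars. T/NK-like cells are 41.2% of the vector library and 1.51% and 3.59% of the KLF2 libraries, and compartment cells are 7.64%, 83.9% and 75.03%. The compartment includes unnamed clusters led by Hbb-bs and by Malat1.

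Klf2, the gene that the labels give as overexpressed, was measured in each class. In the compartment, whose cells are not shown to be tumour cells and differ in type between the groups, its rise was not established. Klf2 (ENSMUSG00000055148.7, GRCm38 chromosome 8, 72319033 to 72321656, plus strand) stood at 167 CPM in the vector compartment and at 326 and 380 CPM in the KLF2 compartments. The fitted change of 0.39 on the log2 scale (SE 0.27) did not pass (adjusted p = 0.349). After thinning each cell to 1000 UMIs, 12.1% (9.76 to 14.9) of vector compartment cells and 22.0% (20.9 to 23.2) and 22.4% (21.5 to 23.3) of KLF2 compartment cells had a Klf2 UMI. T/NK-like cells, which express the gene themselves, had one in 37.9%, 20.2% and 25.1% of cells, at median depths of 2942, 5210 and 3335.5 UMIs against 3231.5, 9412.5 and 6995 in the compartment. Cholangiocyte-like cells of the KLF2 libraries had 357 and 350 CPM. In hepatocyte-lineage-like cells Klf2 was lower in the KLF2 libraries, at 107.9 and 105.4 CPM against 167 in vector, and did not pass in the fit of these few cells (log2 fold change −1.66, adjusted p = 0.428).

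Klf2 fell in T/NK-like cells, from 612 CPM to 339 and 332 (log2 fold change −1.15, adjusted p = 0.00757), but the change was 0.29 in the T/NK cluster found in all libraries. It did not pass in endothelial-like cells (281, 247 and 551 CPM, adjusted p = 0.799), myeloid-like cells (229, 419 and 572 CPM, 0.114), B/plasma-like cells (1135, 1536 and 1467 CPM, 0.792), mesenchymal-like cells (143, 120 and 279 CPM, 0.88) or neutrophil-like cells (677, 1151 and 1013 CPM, 0.746). The species of the KLF2 plasmid and its 3' end are not given in the sources used here, so the UMIs counted as Klf2 include transgene transcripts to an unknown extent.

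**Figure D2:**
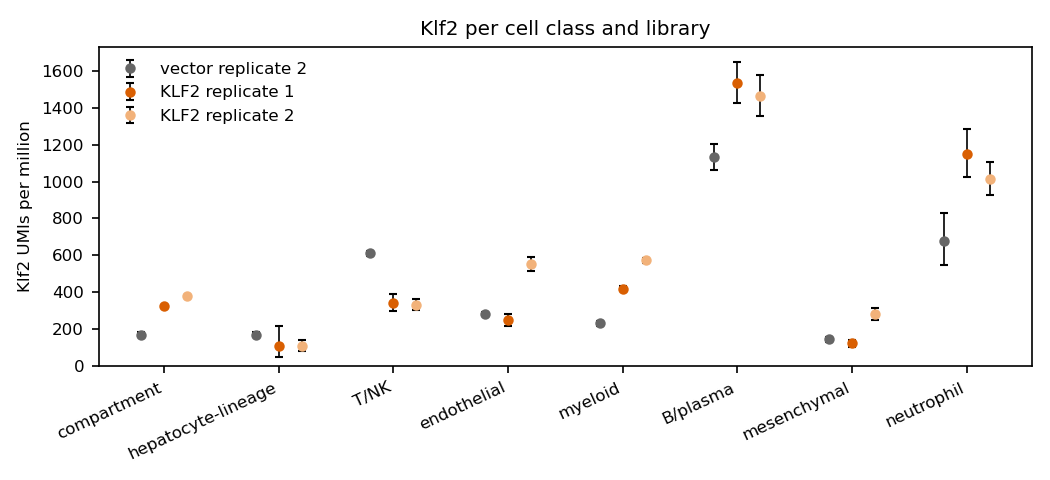
Klf2 level (CPM) in each class of vector replicate 2 and KLF2 replicates 1 and 2, with 95% counting intervals as error bars. In the compartment the values are 167, 326 and 380, and in T/NK-like cells they are 612, 339 and 332.

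The main tumour comparison asked which genes differ between KLF2 and vector in hepatocyte-lineage-like cells. These were 639 vector cells and 20 and 53 KLF2 cells, under the minimum of 50 set for a test. A fit of all 3 libraries whatever their cells, added after seeing the data, called 128 genes higher and 157 lower of 7077. For a count without a test, fewer than 3 UMIs of a gene in a library were set to 3. Of 3452 genes with a mean of at least 30 CPM, 1087 were then at least 2-fold higher and 56 at least 2-fold lower in each KLF2 library. In KLF2 replicate 1, 3 UMIs are 40.5 CPM, so a gene without UMIs there can count as higher. The floor therefore tilts this balance towards rises, and the balance is not a measure of direction. This balance depended on the setting, with 994 higher and 191 lower when mitochondrial and rRNA-overlapping genes were left out and 403 and 107 with equal cells per library. Without KLF2 replicate 2 the counts were 1678 and 179, and after thinning 2196 and 26. Il31ra, a cytokine receptor subunit (chromosome 13, 112519898 to 112594360, minus strand), had no UMI in vector and 809 and 517 CPM in the KLF2 cells. The YAP targets Ccn1 (21.9 CPM in vector, 391 and 384 in KLF2) and Ankrd1 (16.9, 189 and 472), the adhesion receptor Cd44 (31.1, 310 and 280) and the stress factor Atf3 (24.9, 364 and 1003) were higher. So were Cmss1 (23.4, 38990 and 13670), Cdk8 (14.5, 6837 and 3672) and Camk1d (10.2, 5893 and 2308). Apoa4, an apolipoprotein (chromosome 9, 46240696 to 46243459, plus strand), was lower, at 304 CPM against 0 and 2.11, as were the fructose kinase gene Khk (293, 67.4 and 67.5) and the kinetochore gene Spc24 (239, 40.5 and 8.43). The endothelial gene Fabp4 (517, 26.97 and 8.43) and the lymphocyte chemokine Ccl5 (432, 13.5 and 6.32), which belong to other cell types, were also lower. In the added fit Il31ra, Cdk8, Camk1d, Apoa4, Khk, Spc24, Fabp4 and Ccl5 passed. Ccn1 (adjusted p = 0.0885), Ankrd1 (0.0559), Cd44 (0.282), Atf3 (0.0655) and Cmss1 (0.0826) did not. H19, an oncofetal RNA, differed between the KLF2 libraries themselves, at 528 CPM in vector and 3358 and 0 in KLF2. So did Spink1, which is counted below among the oncofetal genes passing in the added fit. It had 1.54 CPM in vector, 3627 in KLF2 replicate 1 and 2.11 in KLF2 replicate 2.

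Of 38 gene lists in these cells, compared in KLF2 replicate 2 alone, 11 had a median shift above and 11 below the central 95% of matched random lists. With KLF2 replicate 1 instead these were 7 and 11 of 37. The random lists themselves shifted up, by medians of 0.33 to 0.68, so each shift below includes a general rise. With the floor of 3 UMIs, 1475 of 3452 genes with a mean of at least 30 CPM were 2-fold higher in KLF2 replicate 2 and 212 lower. Biliary genes had a median log2 shift of 2.25 (16 of 17 at least 2-fold higher, percentile 100 of the random lists). The shift was 2.07 for Wnt target genes (10 of 14 higher and 1 lower, 100), 2.14 for oncofetal genes (10 of 11 higher and 1 lower, 99.99), 1.72 for YAP/TAZ target genes (13 of 15 higher, 100) and 1.86 for acute phase genes (17 of 21 higher and 1 lower, 100). Urea cycle and amino acid genes had −0.72 (6 of 17 lower and 2 higher, percentile 0), fatty acid oxidation genes −0.49 (5 of 17 lower and 2 higher, 0) and G2M genes −0.76 (6 of 15 lower, 0). Hepatocyte secreted protein genes, several of which named these cells, lay among the random lists (0.37, percentile 33.0). Tumour vessel genes, which mark other cells, had −1.27 (percentile 0), and mitochondrially encoded genes −4.81 (0). Dissociation stress genes, a sign of sample preparation, shifted by 1.61, against 0.435 in their random lists (14 of 26 higher and 3 lower, 99.99). In the added fit 6 lists were higher and 10 lower of 37 by camera at the preset correlation. None passed with an estimated correlation, where 1 residual degree of freedom let hardly any list pass. Members passing were 5 of 14 for Wnt target genes and 5 of 13 for oncofetal genes as higher, 4 of 14 for G2M genes as lower, and 1 of 17 biliary and 1 of 16 YAP/TAZ target genes as higher (7, 6, 7, 4 and 3 adjusted over the list alone). No acute phase, urea cycle or fatty acid oxidation gene passed. The urea cycle and amino acid list did not pass camera there either (median −0.33, adjusted p = 0.157), and its members Glul (257 CPM in vector, 4464 in KLF2 replicate 1 and 833 in KLF2 replicate 2) and Mat1a (256, 2576 and 131) were higher in KLF2 replicate 1.

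In the compartment, an added comparison with enough cells for the test, the KLF2 cells lacked most of the hepatocyte programme. Of its 642 vector cells, 639 were hepatocyte-lineage-like, and of the 5212 and 8331 KLF2 cells 20 and 53 were, so the comparison sets hepatocyte-lineage-like cells against mostly other cells. The vector cells were named by hepatocyte markers such as Alb, Apoa1 and Hnf4a, so falls of such genes follow in part from the naming. Fabp1, the liver fatty acid binding protein (ENSMUSG00000054422.7, chromosome 6, 71199827 to 71205023), fell from 4559 CPM to 2.62 and 0.521 (log2 fold change −12.20, SE 1.19, adjusted p = 0.00746). Hnf4a, a master regulator of hepatocyte identity, fell from 46.5 CPM to 0.331 and 1.43 (log2 fold change −6.40, adjusted p = 0.0133). Apoa4 fell from 302 CPM to 3 UMIs over both KLF2 libraries, a ratio with a counting interval of 1.06e-05 to 0.000151. Among the rises were Il31ra, at least 530-fold, from 0 to 425 and 536 CPM (adjusted p = 0.00396), and Ibsp, a bone matrix sialoprotein, at least 111-fold, from 0 to 141 and 71.5 CPM (0.0114). Further rises were Nkain2 (at least 143-fold), Defa21 (at least 150-fold), an intestinal defensin, and Cntn4 (at least 131-fold). Ibsp, Nkain2 and Defa21 had no UMI in any cell of vector replicate 2 and are in the gene list of vector replicate 1. Their 0 may come from how vector replicate 2 was processed, so their folds are not shown to be changes in expression.

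The lists of liver function fell. Of 25 hepatocyte secreted protein genes 24 were lower (24 adjusted over the list alone, camera adjusted p = 1.6e-64). Several of these genes named the vector cells, so this result is not independent of how the cells were picked. Of 20 P450 and bile acid genes 18 were lower (18 adjusted over the list alone, 5.3e-32), such as the xenobiotic oxidase Cyp2e1 (156 to 0.697 and 0.810 CPM). Both lists had an adjusted p of 0.613 with an estimated correlation. Urea cycle and amino acid genes were lower in 17 of 22 (19 adjusted over the list alone, camera adjusted p = 1.0e-38, adjusted p = 0.613 with an estimated correlation), with the ornithine carbamoyltransferase gene Otc falling from 27.3 CPM to 0.059 and 0.14. Hepatocyte transcription factors were lower in 15 and higher in 2 of 20 (16 and 2 adjusted over the list alone, camera adjusted p = 6.0e-12, adjusted p = 0.613 with an estimated correlation). Of 18 fatty acid oxidation genes 11 were lower (13 adjusted over the list alone, camera adjusted p = 1.8e-15, adjusted p = 0.613 with an estimated correlation). Of 20 lipogenesis genes 9 were lower and 1 higher (10 and 1 adjusted over the list alone, camera adjusted p = 3.2e-05, adjusted p = 0.613 with an estimated correlation). An example was the desaturase Scd1 (420 to 50.02 and 46.2 CPM). Genes of antigen presentation were lower in the same cells, in 11 of 15 for MHC class I (14 adjusted over the list alone, camera adjusted p = 6.4e-10) and 8 of 10 for MHC class II (8 adjusted over the list alone, 1.6e-06). Both had an adjusted p of 0.613 with an estimated correlation. The peptide transporter Tap1 fell from 45.0 CPM to 3.47 and 6.78. Cytotoxic lymphocyte genes (11 of 14 lower) and tumour vessel genes (10 of 18 lower), which mark other cell types, fell beside them (13 and 11 adjusted over the list alone, camera adjusted p = 3.7e-11 and 4.9e-08), both with an adjusted p of 0.613 with an estimated correlation. All 13 mitochondrially encoded genes fell, mt-Nd2 from 5676 to 152 and 218 CPM.

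Hypoxia genes rose in 14 of 18 (16 adjusted over the list alone, camera adjusted p = 2.4e-08, adjusted p = 0.613 with an estimated correlation), such as adrenomedullin, Adm (1.53 to 28.9 and 30.7 CPM). Of 17 glycolysis genes 7 rose (10 adjusted over the list alone, camera adjusted p = 0.00119, adjusted p = 0.613 with an estimated correlation). Hexokinase 2, Hk2, rose from 15.9 CPM to 162 and 190 and the lactate transporter Slc16a3 from 3.67 CPM to 112 and 99.4. Wnt target genes rose in 11 and fell in 4 of 18 (11 and 4 adjusted over the list alone, camera adjusted p = 0.00333, adjusted p = 0.613 with an estimated correlation). Lgr5, a Wnt-regulated receptor of intestinal stem cells (chromosome 10, 115450311 to 115587780, minus strand), had 1 UMI in vector and 56.1 and 49.1 CPM in KLF2 (172-fold, counting interval 30.6 to 6732). Stem-cell genes rose in 9 and fell in 2 of 21 (11 and 4 adjusted over the list alone, camera adjusted p = 0.0134, adjusted p = 0.613 with an estimated correlation). The pluripotency factor Sox2 rose from 2 UMIs (0.612 CPM) to 89.4 and 84.9 CPM (142-fold, counting interval 39.3 to 1172). The list of p53 targets rose in 4 of 20 (6 adjusted over the list alone, camera adjusted p = 0.00721, adjusted p = 0.613 with an estimated correlation), among them the cell cycle inhibitor Cdkn1a (898 and 972 CPM in KLF2, log2 fold change 2.95, adjusted p = 0.00889).

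Several plasticity lists moved both ways in the compartment and did not pass camera. Biliary genes were higher in 8 and lower in 4 of 18 (8 and 5 adjusted over the list alone, camera adjusted p = 0.267). The keratin Krt23 rose from 2.45 CPM to 94.0 and 132 and the liver factor Onecut2 fell from 35.2 CPM to 1.89 and 4.62. Oncofetal genes were higher in 8 and lower in 3 of 24 (9 and 4 adjusted over the list alone, 0.264). Bex1 rose from 4.29 CPM to 403 and 332, and the architectural factor Hmga2 (chromosome 10, 120361275 to 120476469, minus strand) from 0 to 11.4 and 18.7 CPM, at least 16.9-fold. H19 fell from 525 CPM to 5.25 and 2.45. Mesenchymal transition genes were higher in 8 and lower in 7 of 30 (12 and 9 adjusted over the list alone, 0.968), the rises including Mmp2, a matrix protease (2.76 to 136 and 80.2 CPM). KLF2-associated genes were higher in 2 and lower in 6 of 18 (2 and 6 adjusted over the list alone, 0.12). Myc (chromosome 15, 61985391 to 61990374, plus strand), a gene of the injected plasmids, rose from 47.1 CPM to 685 and 478 (log2 fold change 2.94, SE 0.40, adjusted p = 0.0137), while Akt1 (269, 1273 and 736 CPM) did not pass (adjusted p = 0.125). The species and 3' ends of the c-MYC and AKT plasmids are not given in the sources used here either, so their transcripts are counted as Myc and Akt1 to an unknown extent. In all, 2642 genes were higher and 2125 lower of 20446 tested. Over these genes the median gene shifted by 0.66 on the log2 scale with TMM scaling and by 0.55 with RLE. Over 27754 genes, without the low-count filter, it shifted by 1.73 with TMM and −0.16 with DESeq2. With limma-voom, chosen after seeing the data, 259 genes were higher and 1137 lower.

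**Figure D3:**
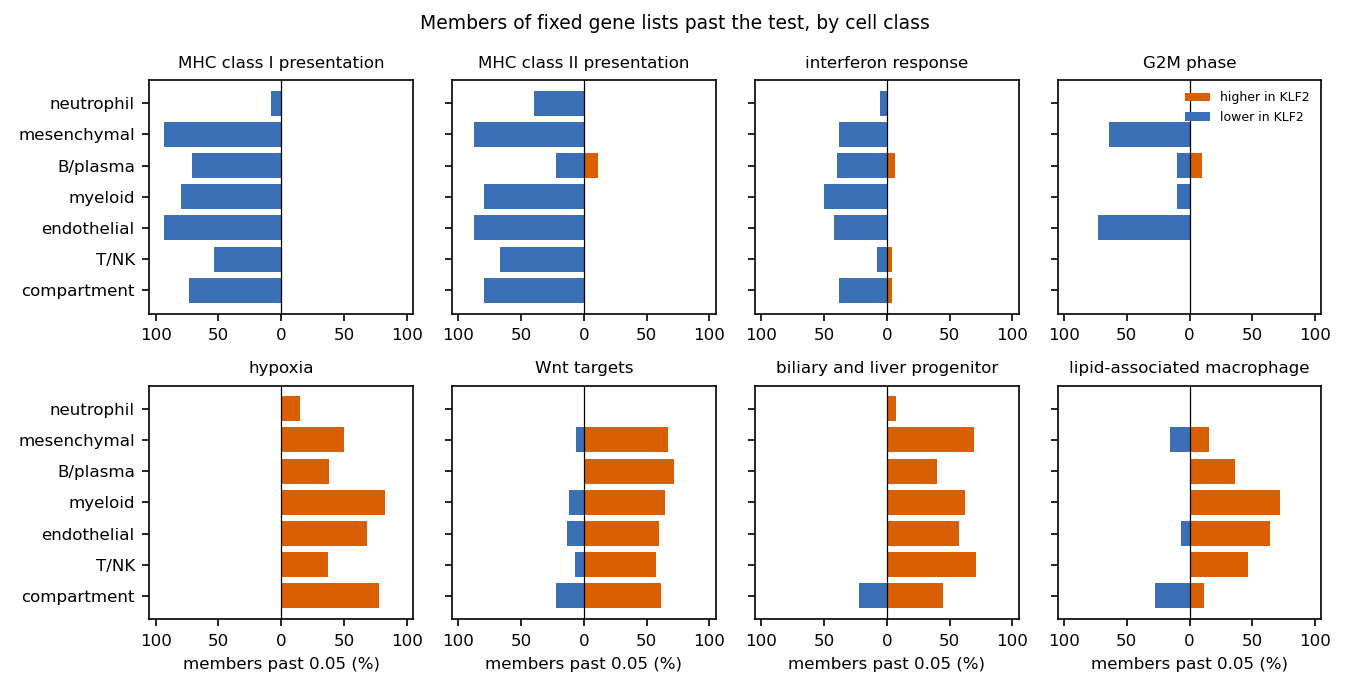
Percent of tested members of 8 gene lists past adjusted p 0.05 as higher (orange) or lower (blue) in the KLF2 libraries, by cell class. MHC class I genes past the threshold as lower range from 1 of 12 in neutrophil-like cells to 14 of 15 in endothelial-like and mesenchymal-like cells, and lipid-associated macrophage genes are higher in 13 of 18 in myeloid-like cells. No list of the figure passed camera in these fits with an estimated correlation, which hardly any list could pass on 1 residual degree of freedom.

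T/NK-like cells were spread over different clusters in the groups. Of 3464 vector cells 2361 lay in a cluster with 6 and 15 KLF2 cells, while 72 of 94 and 344 of 398 KLF2 cells lay in the cluster found in all libraries (1037 vector cells). The granzyme Gzma (chromosome 13, 113093825 to 113100981, minus strand) rose from 26.2 CPM to 664 and 588 (log2 fold change 4.28, adjusted p = 5.4e-07) and Gzmb from 34.4 to 145 and 113 (1.59, 0.00186), while the inhibitory receptor Lag3 fell from 35.7 to 10.1 and 3.68 (−2.92, 0.000486). In the shared cluster the changes were 3.01 for Gzma (adjusted p = 1.64e-15), 0.73 for Gzmb, which did not pass (0.111), and −3.41 for Lag3 (5.98e-11). Across 15 cytotoxic genes 4 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.103), and in the shared cluster 4 rose and 3 fell (5 and 3 adjusted over the list alone, 0.997). Across 12 inhibitory receptors 1 rose, the costimulatory Tnfrsf9 (46.4 to 111 and 120 CPM), and 1, Lag3, fell (1 and 1 adjusted over the list alone, 0.701). In the shared cluster none of the receptors rose and 3 fell (1 and 5 adjusted over the list alone, median −0.61, camera adjusted p = 0.0519), and Tnfrsf9 did not pass (0.58, adjusted p = 0.222). Quiescence genes rose in 3 and fell in 1 of 11 (3 and 1 adjusted over the list alone, 0.709), and in the shared cluster 8 of them rose (8 adjusted over the list alone, median 1.46, camera adjusted p = 9.1e-05, adjusted p = 0.678 with an estimated correlation). In that cluster 1110 genes were higher and 663 lower. MHC class I genes fell in 8 of 15 (9 adjusted over the list alone, camera adjusted p = 0.00026), and dissociation stress genes in 14 of 26 with 1 higher (18 and 1 adjusted over the list alone, 3.8e-08). Both had an adjusted p of 0.821 with an estimated correlation, and in the shared cluster the stress list no longer passed (2 higher, 7 lower, camera adjusted p = 0.121). The heat shock gene Hspa1a fell from 958 CPM to 143 and 230.

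Genes of other cell types moved in these lymphocytes too. Biliary genes were higher in 10 of 14 (11 adjusted over the list alone, 2.7e-07) and Wnt target genes in 8 with 1 lower of 14 (9 and 1 adjusted over the list alone, 3.8e-08), both at an adjusted p of 0.821 with an estimated correlation. Notum, a secreted Wnt inhibitor, rose from 0.303 CPM to 103 and 71.1. Hepatocyte secreted protein genes were lower in 17 of 21 (19, with 1 higher, adjusted over the list alone, camera adjusted p = 1.4e-16) and tumour vessel genes in 10 of 12 (11 adjusted over the list alone, 7.0e-07), again at an adjusted p of 0.821 with an estimated correlation. All 13 mitochondrially encoded genes were lower. The highest rises by rule were Patl2 (at least 1437-fold, 0 to 302 and 336 CPM, adjusted p = 1.5e-08), Nkain2 (at least 821-fold) and Wif1, a Wnt inhibitor (at least 430-fold, 0 to 101 and 96.9 CPM). Fabp1 (132 to 0 and 0.613 CPM) and Fabp4 (318 to 5.04 and 21.5 CPM) fell. In all, 1010 genes were higher and 719 lower of 10733, and with DESeq2 607 and 186. After thinning to 1000 UMIs the balance turned, with more genes lower than higher. The median gene shifted by 0.03 with TMM and 0.02 with RLE over the 10733 genes. Over 21029 genes, without the low-count filter, it shifted by 0.15 with DESeq2 and −0.18 with TMM. Patl2 and Nkain2 are among the genes without any UMI in vector replicate 2 that are in the gene list of vector replicate 1. Both were higher in all 7 tested classes. Their 0 may come from how vector replicate 2 was processed, so their folds are not shown to be rises in T/NK-like cells.

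Endothelial-like cells lay in different clusters by group as well. Of 1718 vector cells 1303 lay in a cluster with 26 of 98 and 56 of 255 KLF2 cells, and the sinusoidal cluster found in all libraries held 296, 54 and 146. Clec4g, a lectin of liver sinusoids (chromosome 8, 3707064 to 3720651, minus strand), rose from 18.9 CPM to 540 and 362 (log2 fold change 4.16, adjusted p = 1.7e-10), and the hyaluronan receptor Lyve1 from 13.8 to 311 and 220 (3.85, 1.0e-09). Sinusoidal genes rose in 12 and fell in 1 of 14 (12 and 1 adjusted over the list alone, camera adjusted p = 9.1e-11, adjusted p = 0.635 with an estimated correlation), and in 9 and 1 of 14 in the sinusoidal cluster found in all libraries. G2M genes fell in 22 of 30 (24 adjusted over the list alone, camera adjusted p = 5.9e-11) and S-phase genes in 17 of 27 (18 adjusted over the list alone, 2.3e-08), both with an adjusted p of 0.635 with an estimated correlation. The proliferation marker Mki67 fell from 122 CPM to 24.0 and 38.0 (log2 fold change −2.32) but did not pass in the shared cluster (−1.12, adjusted p = 0.148). In the shared cluster 4 of 25 G2M genes (9 adjusted over the list alone) and 1 of 18 S-phase genes (0 adjusted over the list alone) fell. The lists there still passed as lower, with medians of −1.39 and −0.96 (camera adjusted p = 8.9e-07 and 0.0067, both with an adjusted p of 0.746 with an estimated correlation). KLF2-associated endothelial genes rose in 5 and fell in 2 of 17 (5 and 2 adjusted over the list alone, camera adjusted p = 0.272), and in the shared cluster 3 rose and 3 fell. The rises included the adhesion molecules Sele (2.30 to 40.7 and 72.6 CPM, adjusted p = 3.2e-09) and Vcam1 (21.2 to 117 and 190, 3.6e-06), which KLF2 is known to restrain in endothelium.

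Tumour vessel genes of the endothelial-like cells rose in 6 and fell in 3 of 18 (6 and 4 adjusted over the list alone, camera adjusted p = 0.863, with a median log2 fold change of −0.09 where camera's direction was up), and in the shared cluster 1 rose and 4 fell of 17 (4 and 9 adjusted over the list alone). There the list passed as lower (median −0.71, camera adjusted p = 0.0067, adjusted p = 0.746 with an estimated correlation). Angpt2, a vessel destabilising factor, rose from 18.5 CPM to 309 and 125 (log2 fold change 3.10) but did not pass in the shared cluster (2.85, adjusted p = 0.0653), and Ly6a fell from 962 to 367 and 315. MHC class I genes fell in 14 of 15 (14 adjusted over the list alone, camera adjusted p = 1.0e-09, adjusted p = 0.635 with an estimated correlation) and in 11 in the shared cluster. Interferon response genes fell in 11 of 26 (13, with 1 higher, adjusted over the list alone, camera adjusted p = 0.00097, adjusted p = 0.635 with an estimated correlation), such as Irf7 (84.7 to 26.1 and 19.98 CPM, log2 fold change −2.29). In the shared cluster 4 of 26 fell (8, with 2 higher, adjusted over the list alone), and Irf7 did not pass (−1.23, adjusted p = 0.0737). Hypoxia genes rose in 11 of 16 (11 adjusted over the list alone, camera adjusted p = 0.00013, adjusted p = 0.635 with an estimated correlation) and in 3 in the shared cluster, where Slc16a3 turned to −0.90 on the log2 scale. Biliary genes were higher in 8 of 14 (9 adjusted over the list alone, camera adjusted p = 7.5e-06) and hepatocyte secreted protein genes lower in 15 of 17 (16 adjusted over the list alone, 1.8e-11), both with an adjusted p of 0.635 with an estimated correlation. All 13 mitochondrially encoded genes were lower. In all, 1383 genes were higher and 1278 lower of 10535, with DESeq2 623 and 279, and in the shared cluster 504 and 385. After thinning to 1000 UMIs the balance turned, with more genes lower than higher.

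Myeloid-like cells also lay in different clusters by group, with 670 of 683 vector cells in the monocyte-like cluster found in all libraries against 92 of 564 and 252 of 1637 KLF2 cells. The class as a whole therefore compares mostly different clusters. Arginase 1, Arg1 (chromosome 10, 24915221 to 24927484, minus strand), rose from 3.78 CPM to 4694 and 840 (log2 fold change 9.21, adjusted p = 0.00712). Osteopontin, Spp1 (chromosome 5, 104435118 to 104441050, plus strand), rose from 36.4 to 2419 and 2168 (5.68, 0.000874) and the neutrophil chemoattractant Cxcl2 from 25.6 to 2217 and 1561 (5.90, 0.000915). The interferon-induced chemokine Cxcl9 fell from 812 to 82.1 and 122 (−3.29, 0.00184). In the shared cluster the changes were 2.74 for Arg1, 2.98 for Cxcl2 and −2.59 for Cxcl9, all past 0.05, while Spp1 did not pass (0.60, adjusted p = 0.287). Lipid-associated macrophage genes rose in 13 of 18 (14 adjusted over the list alone, camera adjusted p = 2.1e-09) and Kupffer cell genes rose in 7 and fell in 1 of 11 (9 and 1 adjusted over the list alone, 3.8e-05), both with an adjusted p of 0.562 with an estimated correlation. Inflammatory genes rose in 6 and fell in 1 of 14 (7 and 1 adjusted over the list alone, camera adjusted p = 0.0037), and hypoxia genes in 14 of 17 (15 adjusted over the list alone, 7.5e-09). These had the same adjusted p of 0.562 with an estimated correlation. The angiogenic factor Vegfa rose from 2.98 CPM to 131 and 96.4.

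In the same class 13 of 26 interferon response genes fell (14 adjusted over the list alone, camera adjusted p = 9.4e-08, adjusted p = 0.565 with an estimated correlation). MHC class I genes fell in 12 of 15 (13 adjusted over the list alone, 1.1e-11) and MHC class II genes in 8 of 10 (8, with 2 higher, adjusted over the list alone, 3.9e-05), both with an adjusted p of 0.562 with an estimated correlation. Ciita, the class II transactivator, fell from 166 CPM to 33.1 and 32.8 (log2 fold change −2.63) but did not pass in the shared cluster (−0.80, adjusted p = 0.0548). In the shared cluster the interferon and class I falls were 13 of 25 and 11, class II genes fell in 2 (4 adjusted over the list alone, camera adjusted p = 0.0778) and hypoxia genes rose in 7. Kupffer cell genes rose in 1 and fell in 1 of 6 there (1 and 1 adjusted over the list alone, median −1.11, camera adjusted p = 0.433) and inflammatory genes rose in 4 and fell in 2 of 12 (5 and 2 adjusted over the list alone, 0.439), so neither list passed. The lipid-associated macrophage list turned, with 3 higher and 9 lower of 15 (3 and 9 adjusted over the list alone, camera adjusted p = 0.0218, adjusted p = 0.713 with an estimated correlation). Biliary genes were higher in 10 of 16 (11 adjusted over the list alone, camera adjusted p = 2.4e-06) and hepatocyte secreted protein genes lower in 19 of 24 with 1 higher (20 and 2 adjusted over the list alone, 2.4e-21), both with an adjusted p of 0.562 with an estimated correlation. In all, 1803 genes were higher and 1112 lower of 13883, in the shared cluster 847 and 735, and with limma-voom 220 and 421. The median gene shifted by 0.14 with TMM and 0.09 with RLE over the 13883 genes. Over 22649 genes, without the low-count filter, it shifted by 0.55 with TMM and 0.23 with DESeq2.

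In B/plasma-like cells the deepest falls included a pair of immunoglobulin genes. Ighg1 (chromosome 12, 113325240 to 113330523, minus strand) fell from 570 CPM to 0 in each KLF2 library, at least 176-fold (adjusted p = 8.6e-12), and Ighg2c from 151 CPM to 0, at least 46.4-fold. Immunoglobulin RNA also fell in classes that do not make it, such as Igkc in neutrophil-like cells (3365 to 7.29 and 4.21 CPM), mesenchymal-like cells (230 to 1.48 and 0.842 CPM) and T/NK-like cells (214 to 26.9 and 15.9 CPM). The homing receptor Ccr7 rose from 145 to 404 and 457 CPM (log2 fold change 1.36, 0.0205). MHC class I genes fell in 10 of 14 (11 adjusted over the list alone, camera adjusted p = 1.9e-08) and Wnt target genes rose in 10 of 14 (11 with 1 lower adjusted over the list alone, 1.2e-08), both with an adjusted p of 0.792 with an estimated correlation. Genes of other cells moved with the group, with the cytotoxic gene Nkg7 at 155 CPM in vector and 0 and 4.39 in KLF2. In all, 480 genes were higher and 417 lower of 6348, and with DESeq2 106 and 48. After thinning to 1000 UMIs 34 passed.

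Mesenchymal-like cells had lower proliferation and antigen presentation genes and higher genes of the TGF-beta response list in the KLF2 libraries, beside changes in genes of other cell types. Fabp1 (149 to 0 and 0 CPM) fell and Krt7 (0 to 48.1 and 122 CPM) and Wif1 (0 to 93.3 and 158 CPM) rose, and mitochondrially encoded genes had a median log2 fold change of −4.52. G2M genes fell in 16 of 25 (21 adjusted over the list alone, camera adjusted p = 1.9e-10), MHC class I genes in 14 of 15 (14 adjusted over the list alone, 4.9e-14) and MHC class II genes in 7 of 8 (8 adjusted over the list alone, 7.1e-10), each with an adjusted p of 0.651 with an estimated correlation. The mitotic kinase Plk1 fell from 39.4 CPM to 9.63 and 1.69, and the invariant chain Cd74, abundant in immune cells, from 669 to 35.5 and 95.2. TGF-beta response genes rose in 10 and fell in 1 of 19 (10 and 1 adjusted over the list alone, camera adjusted p = 0.00381, adjusted p = 0.651 with an estimated correlation), including Id1 (21.3 to 156 and 169 CPM). Id1 is also a target of BMP signalling, so the rise does not single out TGF-beta. NF-kB target genes fell in 9 and rose in 3 of 20 (11 and 4 adjusted over the list alone, camera adjusted p = 0.00087, adjusted p = 0.737 with an estimated correlation), among them Cxcl9 (316 to 0.74 and 22.7 CPM), which fell in myeloid-like cells too. Pdgfra, a fibroblast receptor, rose from 26.9 CPM to 108 and 179 (adjusted p = 0.00241). The contractile genes Tagln (1812, 1807 and 495 CPM) and Acta2 (1507, 1587 and 651 CPM) also passed as lower, but in KLF2 replicate 1 they were level with vector. In all, 1227 genes were higher and 996 lower of 10983, and 419 passed after thinning. With limma-voom the balance turned, with more genes lower than higher.

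Neutrophil-like cells, the smallest class with 70, 58 and 143 cells, had higher Cxcl2 (402 to 10450 and 8545 CPM, log2 fold change 4.15, adjusted p = 0.0132). Genes of other cells moved with it, with Krt7 at 0 CPM in vector and 179 and 322 in KLF2, Ccl5 at 1265, 3.64 and 35.8, and Alb at 149, 0 and 4.21, and mt-Nd2 fell from 8337 CPM to 54.6 and 154. MHC class I genes fell in 1 of 12 (11 adjusted over the list alone, camera adjusted p = 1.4e-08) and hypoxia genes rose in 2 of 13 (7 adjusted over the list alone, 6.5e-05), both with an adjusted p of 0.631 with an estimated correlation. In all, 42 genes were higher and 58 lower of 4475. This balance depended on the setting, with 270 and 244 with RLE size factors, 38 and 25 with DESeq2, 5 and 31 with limma-voom, and 323 and 199 without mitochondrial and rRNA-overlapping genes. The median gene shifted by 0.35 with TMM and 0.24 with RLE over the 4475 genes. Over 15530 genes, without the low-count filter, it shifted by 1.59 with TMM and 0.37 with DESeq2.

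A small set of genes moved in all 7 tested classes. Of 3868 genes tested in each, 28 were higher and 31 lower in every class, where 0.000284 and 6.4e-05 would be met if classes were independent. The genes higher in all included Myc, Il31ra, Wif1, Patl2, Apcdd1, Krt7, Cmss1, Camk1d and Gphn, and those lower in all included Fabp1, Apoa2, Alb, Fabp4, Tap1 and mitochondrially encoded genes. All classes of a library come from the same mouse and preparation, so they are not independent.

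The last comparison asked about plasticity per cell, at a fixed depth of 1000 UMIs. Hepatocyte-lineage-like cells had a median of 338 genes in vector (617 cells) and 438.5 and 525 in KLF2 (20 and 53 cells). With mitochondrial and rRNA-overlapping genes left out before thinning, a setting chosen after seeing the data, the medians were 605, 608 and 659. At least 2 biliary genes were found in 9.24% (7.20 to 11.8) of these cells in vector and in 35.0% (18.1 to 56.7) and 83.0% (70.8 to 90.8) in KLF2. At least 2 oncofetal genes were found in 12.6% (10.2 to 15.5), 40.0% (21.9 to 61.3) and 43.4% (31.0 to 56.7). T/NK-like cells had biliary genes in 2.26%, 17.0% and 24.1% and oncofetal genes in 6.16%, 23.4% and 25.1%, at median depths of 2942, 5210 and 3335.5 UMIs against 3191, 2286.5 and 4746. Both lists hold genes that T cells can express, such as Cd44 and Ly6e (oncofetal) and Anxa2 and Lgals3 (biliary). These T/NK shares are therefore not a pure background level. Mesenchymal genes were found in 70.5%, 80.0% and 96.2% of hepatocyte-lineage-like cells and in 93.5%, 98.9% and 98.7% of T/NK-like cells. That list holds genes that T cells express, such as Vim, S100a4 and Tmsb10, so the T/NK share gives no background level for it. At least 2 G2M genes were found in 12.3% (9.96 to 15.1), 5.0% (0.888 to 23.6) and 1.89% (0.334 to 9.94) of hepatocyte-lineage-like cells, against 11.1%, 9.83% and 8.87% of cells outside the compartment. In the whole compartment these shares were 12.3%, 16.7% and 11.2%, so the KLF2 libraries lay on either side of vector.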

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

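The classes were compared in a single model added after the results were seen. Its 6 residual degrees of freedom came from differences between the same 2 KLF2 mice across classes. Classes of a mouse thus stood in for replicates, and its p-values and gene counts cover no spread between vector mice. The tests of ribosomal protein genes, of the vector replicate 1 gene list and of Myc in the vector library were also chosen only afterwards. So was the test of the setting without mitochondrial and rRNA-overlapping genes.

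The change with KLF2 in the compartment differed from the mean change of the other classes for 1367 of 14683 genes (137 higher, 1230 lower, edgeR with 6 residual degrees of freedom). The same test gave 160 genes in T/NK-like cells (116 higher, 44 lower), 302 in endothelial-like cells (141 and 161), 85 in myeloid-like cells (64 and 21), 30 in B/plasma-like cells (24 and 6), 229 in mesenchymal-like cells (52 and 177) and 172 in neutrophil-like cells (161 and 11). In the compartment, lipogenesis genes changed by a median of −2.47 on the log2 scale relative to the other classes (camera adjusted p = 0.0208 with an estimated correlation), fatty acid oxidation genes by −2.31 (0.0208) and oxidative phosphorylation genes by −0.8 (0.049). In T/NK-like cells the relative change was 0.8 for T cell inhibitory receptors and 2.22 for regulatory T cell genes (both 0.0366). In the T/NK-like cells themselves these lists had medians of −0.16 and 0.28 (camera adjusted p = 0.701 and 0.71), and in their shared cluster −0.61 and −0.03, so the relative changes do not show a rise in T cells. For endothelial-like cells the relative change was 2.34 for tumour vessel genes (0.00528). In endothelial-like cells themselves these vessel genes had a median change of −0.09 (camera adjusted p = 0.863) and in their shared cluster −0.71 (0.0067, adjusted p = 0.746 with an estimated correlation), while 10 of 12 fell in T/NK-like cells and 10 of 18 in the compartment.

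In all 7 tested classes mitochondrially encoded genes were lower and Cmss1, Camk1d, Cdk8, Gphn and Jarid2 higher in the KLF2 libraries. Nuclei, or cells that lost their cytoplasm, throughout all classes are argued against by ribosomal protein genes, whose median log2 fold change had a median of 0.001 over 6 classes (−0.54 to 0.614). The bound for this test was set after seeing the data. Mesenchymal-like (−0.54), myeloid-like (−0.496) and endothelial-like cells (−0.177) had negative medians. The test cannot exclude such a loss in a single class or in part of the cells. More UMIs from introns in the KLF2 libraries cannot be told from a change in expression, since genes with the longest introns lay above those with the shortest by a median of 0.973 on the log2 scale and by at least 1 in 3 of the 6 classes. Different processing of vector replicate 2 may underlie part of the pattern. The order of the gene list of vector replicate 1 matched the KLF2 libraries (Spearman 1.0) and not vector replicate 2 (−0.12, across genes, which are not independent replicates). A total of 77 genes with at least 1000 UMIs in each KLF2 library had none in vector replicate 2, and 100% of these were in that list. So were all 8329 genes with at least 1000 UMIs in each KLF2 library, so the 100% is a base rate and adds no support. Whether KLF2 also contributes stays open, because the processing and the group cannot be told apart without counts from another vector mouse.

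Biliary, Wnt target and oncofetal genes were higher in the KLF2 libraries in T/NK-like, endothelial-like, myeloid-like, B/plasma-like and mesenchymal-like cells. In that order the members higher were 10 of 14, 8 of 14, 10 of 16, 4 of 10 and 9 of 13 for biliary genes, 8 of 14, 9 of 15, 11 of 17, 10 of 14 and 10 of 15 for Wnt target genes, and 6 of 13, 6 of 13, 9 of 15, 4 of 7 and 8 of 16 for oncofetal genes. With an estimated correlation none of these lists passed (lowest adjusted p = 0.562), and in the shared endothelial cluster oncofetal genes were higher in 3 and lower in 1 of 12 (camera adjusted p = 0.182). A candidate source is RNA of compartment cells in the droplets of other cells, free or from mixed droplets. Among the members that rose, the level in a class followed that in the compartment of the same library with a median Spearman coefficient of 0.824, at 0.7 or above in 9 of 10 class and library pairs (0.594 in mesenchymal-like cells of KLF2 replicate 1), across genes. Their levels were a median of 14.0% to 37.0% of the compartment's. The source cannot be told apart from expression in these cells, since neutrophil-like cells had 1 such member and gave no coefficient and since no measurement of empty droplets was used here.

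Hepatocyte transcripts were nearly absent from most KLF2 compartment cells. Counts taken up by mitochondrial and rRNA-overlapping genes are argued against as the cause by their direction. They took more UMIs in vector (median mitochondrial share 16.3%, Gm42418 25.6%) than in KLF2 (0.227% and 0.35%, 12.1% and 15.8%). That would lower other genes in vector and not in KLF2. Without these genes 24 of the 25 hepatocyte secreted protein genes were still lower. That count cannot decide, since such genes also named the vector cells. A vector library that holds few counterparts of the KLF2 compartment cells cannot be told apart from a change of state: Myc in the vector hepatocyte-lineage-like cells was 2.08 times the median of the other vector classes, between the bounds of 2 and 4 set for the test. Loss of hepatocyte identity with KLF2 stays open: in the added fit of hepatocyte-lineage-like cells none of 25 hepatocyte secreted protein genes passed, but those cells were named by such genes. Whether the tissue of the KLF2 libraries is as labelled was not tested and stays open as well, which bears on every compartment value.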

How the results depend on the processing

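Removal of the top 5% of doublet scores, no mitochondrial limit, mitochondrial and rRNA-overlapping genes left out, limma-voom for counts of genes, shared clusters and the fit of hepatocyte-lineage-like cells were chosen only after the results were seen. Of the values that answer a comparison, 290 stayed the same under an alternative, 88 moved and 3 reversed. For shares, Klf2 levels and values per cell, the same meant within the SD of the 2 KLF2 libraries. Leaving out 1 KLF2 library could therefore hardly give anything but the same or a reversal. Those cases are counted among the same but are no sign of stability. Among single named genes and other values 12269 stayed the same, 1257 kept their direction but no longer passed, 58 passed newly, 22 moved and 8 reversed. RLE size factors kept all of the 171 named calls of the compartment, and DESeq2 kept 169 of them, but limma-voom kept 121. DESeq2 kept 74 of 131 in T/NK-like, 87 of 153 in endothelial-like, 32 of 88 in B/plasma-like and 66 of 137 in mesenchymal-like cells. Limma-voom kept 83 of 161 in myeloid-like cells, and shared clusters kept 82 of 133 in endothelial-like cells. Depth limits the results, since thinning to 1000 UMIs kept 129 of 153 testable calls in the compartment and 8 of 59 in B/plasma-like cells. No paired analysis was possible because no matrix of vector replicate 1 was analysed here, so no replicate number could serve as a block. DESeq2 for gene lists was not run, as camera does not use it. In hepatocyte-lineage-like cells the alternative tests and filters of low counts were not run, and the only fit there was the added one of all 3 libraries (128 genes higher and 157 lower of 7077). Neutrophil-like cells gave no fit with 500 genes or 10% mitochondrial UMIs. The cause was not tested for any of the changes that follow, other than fewer cells or UMIs under thinning and equal cells.

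The number of genes past 0.05 was 4767 in the compartment and became 2765 after thinning and 1396 with limma-voom. In T/NK-like cells (1729) it was 793 with DESeq2, 1132 at resolution 0.5, 1146 without doublet removal, 703 after thinning, 597 with equal cells and 2618 with limma-voom. In endothelial-like cells (2661) it was 902 with DESeq2, 1119 after thinning, 1208 with equal cells and 889 in shared clusters. In myeloid-like cells (2915) it was 4727 without the low-count filter, 1817 with DESeq2, 1828 at resolution 2.0, 1267 after thinning, 1582 in shared clusters and 641 with limma-voom. In B/plasma-like cells (897) it was 154 with DESeq2, 431 with 10% mitochondrial, 523 without the top 5% of doublet scores, 34 after thinning and 507 with limma-voom. In mesenchymal-like cells (2223) it was 622 with DESeq2, 419 after thinning, 949 with equal cells and 1183 with limma-voom. In neutrophil-like cells (100) it was 514 with RLE, 425 without the low-count filter, 63 with DESeq2, 402 at resolution 0.5, 329 with no mitochondrial limit, 192 without the top 5% of doublet scores, 522 without mitochondrial and rRNA-overlapping genes, 35 after thinning and 36 with limma-voom.

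The number of gene lists past 0.05 was 7 in T/NK-like cells with equal cells, 15 in myeloid-like cells in shared clusters, and after thinning 10 in endothelial-like, 4 in B/plasma-like, 11 in mesenchymal-like and 8 in neutrophil-like cells. Neutrophil-like cells also had 23 without the low-count filter and 9 with equal cells. In hepatocyte-lineage-like cells 2222 genes were 2-fold apart after thinning, 510 with equal cells and 1687 to 1857 with 1 KLF2 library left out. These counts include genes raised to the floor of 3 UMIs, which weighs more the fewer UMIs a library holds.

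Shares are given as the KLF2 mean minus vector in percentage points. At resolution 0.5 they were −7.076 for hepatocyte-lineage-like, −20.004 for endothelial-like and −12.498 for unnamed cells, and at resolution 2.0 they were 2.898 for cholangiocyte-like and −15.03 for unnamed cells. With 500 genes they were −6.713 for hepatocyte-lineage-like, −42.04 for T/NK-like, −22.256 for endothelial-like, −3.386 for mesenchymal-like and 0.615 for neutrophil-like cells, and they reversed for myeloid-like (−4.486) and unnamed cells (1.379). With 10% mitochondrial they were −6.523 for hepatocyte-lineage-like, −22.966 for endothelial-like, −0.903 for B/plasma-like, −4.828 for mesenchymal-like, 0.855 for neutrophil-like and −2.675 for unnamed cells, and reversed for myeloid-like cells (−3.005). With no mitochondrial limit they were −7.078 for hepatocyte-lineage-like, −36.394 for T/NK-like, −17.684 for endothelial-like, −2.681 for B/plasma-like, −2.278 for mesenchymal-like, 0.005 for neutrophil-like and −17.116 for unnamed cells. Without the top 5% of doublet scores they were −2.596 for mesenchymal-like and −13.032 for unnamed cells.

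Per cell in hepatocyte-lineage-like cells, the KLF2 mean minus vector without mitochondrial and rRNA-overlapping genes was 28.5 genes, −19.582 percentage points for cycling and 20.545 for oncofetal genes. Thinned to 500 UMIs it was 74.25 genes, −1.564 for cycling and 9.426 for oncofetal genes, thinned to 2000 UMIs 250.5 genes, 37.808 for oncofetal and 5.037 for mesenchymal genes, and not thinned 421 genes, −12.765 for cycling, 36.756 for oncofetal and 5.321 for mesenchymal genes. Cycling in the compartment (1.69 points) reversed without mitochondrial and rRNA-overlapping genes (−16.337), at 2000 UMIs (−8.44) and without KLF2 replicate 1 (−1.071), and was 4.453 without KLF2 replicate 2. The log2 ratio of Klf2 in the compartment was 0.681 as a mean of UMIs per 10000 per cell, and the share of compartment cells with a Klf2 UMI differed by 5.897 points at 500 UMIs and by 26.538 not thinned. In shared clusters Klf2 reversed in sign in T/NK-like cells (0.285), Slc16a3 in endothelial-like cells (−0.899), and Hmox1 (−0.763), Vcam1 (−3.007) and Plk2 (−0.082) in myeloid-like cells. Of these only Vcam1 passed in the new direction.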

Other observations

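The KLF2 compartment was made of clusters whose leading genes belong to several tissues, described here as values with no test. Whether the tissue of these libraries is as labelled was not tested. A cluster led by the bone and matrix genes Ibsp, Serpinf1, Col1a1 and Sparc held 956 and 468 cells in KLF2 replicates 1 and 2 and 0 in vector. The cluster led by the synaptic adhesion genes Cntn4 and Lsamp and the glutamate receptor gene Grik1 held 847 and 885 KLF2 cells and 0 vector cells. Another, led by the intestinal defensins Defa21 and Defa22 and the hair keratins Krt84 and Krt36, held 53 and 171 KLF2 cells and 0 vector cells. The largest, led by Car3, Fxyd6, Prss56 and Mt3, held 1396, 1953 and 2 cells in KLF2 replicate 1, KLF2 replicate 2 and vector at a median of 16217 UMIs, and a cycling cluster led by Ube2c and Top2a held 266, 352 and 1. Clusters with leading genes of blood (Hbb-bs; 306, 1413 and 0 cells at a median of 1758 UMIs) and of nuclear RNA (Malat1; 465, 1126 and 0 cells) were also in the compartment.

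Single genes of BMP and Wnt signalling rose in the compartment, with no list of BMP targets tested. Id3 rose from 56.3 CPM to 1222 and 1127 (log2 fold change 3.69, adjusted p = 0.00711) and Id1 from 23.6 to 511 and 440 (3.65, 0.00698), both targets of BMP signalling, and the ligand Bmp2 from 3 UMIs (0.918 CPM) to 62.6 and 57.8 CPM (65.6-fold, counting interval 22.3 to 316.5). The Wnt effector Lef1 rose from 3.67 to 126 and 126 CPM, and the Wnt target list had an adjusted p of 0.613 with an estimated correlation. Of 22 YAP/TAZ target genes 5 rose and 3 fell (9 and 6 adjusted over the list alone, camera adjusted p = 0.705), and of 19 TGF-beta genes 4 rose and 2 fell (5 and 3 adjusted over the list alone, 0.145). Among the myeloid clusters, the one led by Saa3, Arg1 and Cxcl2 held 191, 50 and 0 cells, and the one led by Mmp12, C1qa, Apoe and Spp1 held 208, 1029 and 2 cells in KLF2 replicate 1, KLF2 replicate 2 and vector.

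Vector replicate 1, of which no counts were used, listed 10493 barcodes and 24505 genes, against 12852 and 23421 for vector replicate 2. Of 3717 genes listed for both KLF2 libraries and not for vector replicate 2, 2710 (72.9%) were listed for vector replicate 1, and of 809 genes listed for vector replicate 2 and neither KLF2 library 112 (13.8%) were. All 8329 genes with at least 1000 UMIs in each KLF2 library were listed for vector replicate 1.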
